A study of Mus musculus with 3 samples.

How the data were processed

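The series holds 3 arrays of C2C12 myoblasts arrested in G0. Per the labels, the cells were held in suspension in 2% methylcellulose, fixed with 1% formaldehyde and quenched with 0.125 M glycine, and chromatin was precipitated with an antibody against PRDM2 on 2 arrays and against H3K9me2 on 1 array. Immunoprecipitated DNA was labelled with Cy5 and input DNA with Cy3 on every array, with no exchange of dyes. The arrays were a custom 2-colour Agilent design of mouse promoters with 243504 spots and probes of 45 to 60 nt. The antibodies themselves and separate cultures are not described in the labels.

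Per the file headers, the deposited processed intensities had been made by Agilent Feature Extraction 10.5.1.1 with its ChIP protocol, by spatial detrending, subtraction of a background taken from negative-control spots, multiplicative detrending, linear dye normalization and surrogate values for spots not above background. Per the file headers, the deposited raw intensities were the mean signal of each spot and the median of its local background, without normalization. The log10 ratios in the deposited scanner files were those of red over green processed signal, and they were used only as a check of the processed signals. The flags in the deposited scanner files, of 0 or 1 per the file headers, marked control, saturated, outlier and well-above-background spots, and surrogate columns held the value used in place of a dim signal. A deposited value table by the authors held values on a log2 scale of IP over input, a unit taken from its comparison with the scanner files; its medians were 0.124, 0.103 and 0.278, its correlation with the log2 ratio of the same probes was 0.965, 0.940 and 0.972, and the tool that made it is not given in the sources used here. Probe coordinates were those of the array design, and their genome build is not given in the sources used here.

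The log2 ratio of red over green processed signal was taken for 237203 probes outside the controls, outlier spots (773, 107 and 218 on PRDM2 arrays 1 and 2 and the H3K9me2 array) were left out, and each array was centred on its median probe. Probes with 1 gene name were grouped into promoters, which were split where neighbouring probes lay over 10000 bp apart. This gave 16483 promoters with a median of 15 probes, a median spacing of 174 bp and a median span of 3401 bp, and the promoter value was the mean of its probes. A promoter needed at least 3 probes on every array, which left 16164. Of the 16079 gene names tested, 12985 were current symbols, 2750 were matched as a synonym of 1 gene and 344 were unmatched; names are given as on the array. The 5776 probes without a gene name entered only the tests per probe and the search for regions.

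PRDM2 log2 ratios were tested against 0 per promoter and per probe with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05. The difference of PRDM2 and H3K9me2 was tested with limma on all 3 arrays, where the lone H3K9me2 array is assumed to vary as the PRDM2 pair does. Gene lists were tested with camera of limma on the PRDM2 arrays at the preset correlation of 0.01 and also with an estimated correlation, adjusted over 31 lists. The estimated correlation leaves camera with only the residual degrees of freedom of 2 arrays, so that hardly any list could pass. List medians of PRDM2 and of H3K9me2 were compared with 10000 random lists matched on probe number, capped at 25 probes. The promoters drawn for random lists included members of the list tested, so that lists matched on low GC content held many receptor promoters. Regions were runs of at least 3 probes with gaps of at most 1000 bp, above the 95th percentile of the array, in both arrays for PRDM2, beside 100 shuffles. The overlap of promoters with regions was compared with 1000 shuffles of promoters matched on probe number, with and without GC content in 20 classes. Further tools were data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

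The comparisons, tests, the rule for names, the 32 gene lists and most alternatives were chosen before the data were examined. The rule named the 10 promoters with the highest and the 5 with the lowest PRDM2 mean among those past the threshold with the same sign on both arrays, the 10 highest H3K9me2 values, the 10 highest by the lowest of the 3 arrays, the 5 largest differences each way with both PRDM2 arrays on the same side of the H3K9me2 array, the 5 highest PRDM2 regions, Ccna2, Myog, Myod1, Id3 and Prdm2 in any case, and in each list up to 4 members by the size of the PRDM2 mean, of which the text gives the first 1 or 2, or 4 for the canonical histones. Predicted genes were counted and passed over, and 1 promoter that the rule named is not reported here. The lists covered cyclins and CDKs, DNA replication, mitosis, the E2F and RB family, CDK inhibitors and the p53 pathway, myogenic regulators, muscle structure, quiescent satellite cells, histone lysine methylation, Polycomb, Hox genes, developmental transcription factors, the Wnt, TGF-beta and FGF pathways, ribosomal proteins, oxidative phosphorylation, housekeeping, canonical histones, germline, neuronal, immune, cytokine, liver, keratin, extracellular matrix, immediate early, imprinted, olfactory receptor, vomeronasal receptor, zinc finger and microRNA genes.

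Alternatives were normexp background correction with an offset of 50 on the raw signals, loess within each array, only probes with input well above background on every array, the value table, removal of the trend on probe GC content (bins of 2% with at least 200 probes), outlier spots kept, the median over probes or the highest mean of 3 neighbouring probes per promoter, at least 5 probes, a variance trend, adjusted p under 0.10, other percentiles and run lengths, and leaving out each PRDM2 array. Centring on the median promoter, alone and with the GC trend removed, random lists and shuffles matched on GC content, regions after removal of the GC trend and list medians under other scalings were added after the data were examined.

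The tests were run on simulated data. Of 50 promoters shifted by 1 on the log2 scale, limma called 45 upward and 47 downward, and all 50 each way for a shift of 2, with 14 other calls among 16164. For the difference it called 11 and 9 of 50 for a shift of 1, and 50 and 48 for a shift of 2, with 9 other calls. Camera of limma gave a p of 4.97e-36 for a shifted list of 40 promoters and 0.199 for an unshifted one. In these limma and camera simulations every promoter not shifted had a true value of 0, in independent noise without a GC trend. The simulated H3K9me2 array was given the spread of the PRDM2 arrays. The numbers of other calls and the camera p therefore do not carry over to the real arrays. In a separate simulation the random lists placed a shifted list at percentile 99.4 and an unshifted one at 86.9. The search for regions found 144 of 144 planted runs and 0 others. Those runs were shifted by 5 SD in independent noise without a GC trend, so that the 0 does not carry over to the real arrays. A position relative to the transcription start was not computed, since the coordinates of 8.72% of 13106 genes lay within 10 kb of those in the reference used here. Groups of 2 and 1 arrays were too small for a test of single arrays against their group or for other splits of the arrays.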

Results

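Chromatin of C2C12 cells, a mouse myoblast line, was immunoprecipitated after the cells had been arrested in G0 in suspension, and the DNA was hybridised to a custom array of mouse promoters. The antibodies recognised PRDM2, a zinc finger protein with a known histone H3 lysine 9 methyltransferase domain, and H3K9me2, the dimethylated form of that lysine and a mark of silent chromatin. Per the labels, 2 arrays carried PRDM2 DNA and 1 array carried H3K9me2 DNA, each beside its own input DNA in the other dye. An array of a control antibody was not used here. Each array held 237203 probes outside the controls, of which 231427 carried a gene name, and 16164 promoters had at least 3 usable probes. The median IP signal was 1.47 and 1.39 times that of the negative-control spots on PRDM2 arrays 1 and 2, and 6.44 times on the H3K9me2 array. The median input signal was 3.48, 4.66 and 6.12 times that of the negative controls on the same arrays. IP signal was well above background at 75.7%, 71.1% and 78.9% of the probes, and input signal at 98.0%, 99.02% and 92.8%. The number of arrays limits the precision of every value below. Since the labels do not say whether the PRDM2 arrays came from separate cultures, the p-values measure only the spread between these samples. Errors of PRDM2 values are the SD of 2 arrays (n = 2), and the H3K9me2 values have no replicate.

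The first comparison, of PRDM2 IP over input, addressed which genes PRDM2 occupies in arrested myoblasts, the question that the series title names. Ratios are given relative to the median probe of each array, which before centring lay at -0.91 and -0.80 on PRDM2 arrays 1 and 2 and at -0.27 on the H3K9me2 array. Enriched and depleted thus mean above and below the median probe, not more or less IP than input. The promoters with the highest PRDM2 IP over input belonged to genes of varied function. Whdc1, which drives actin branching at membranes, had a mean log2 IP over input of 3.81 ± 0.47. Pcgf2, a subunit of Polycomb repressive complex 1, stood at 3.60 ± 0.44 and Tmem63b, a mechanically gated ion channel, at 3.52 ± 1.23. Centg1, a GTPase-activating protein, followed at 3.49 ± 0.11 and Zbtb1, a zinc finger repressor needed for lymphocytes, at 3.39 ± 0.19. Cdkn2a, which encodes inhibitors of the cell cycle, stood at 3.39 ± 0.75, but its input was well above background at only 7 and 10 of 22 probes on the PRDM2 arrays. That input lay at -4.22 and -3.99 log2 relative to probes of like GC content. A ratio over so little input can be high at low IP signal and does not show PRDM2 enrichment. Kcna7, a potassium channel, had 3.37 ± 0.37, Arcn1, a coat protein of transport vesicles, 3.34 ± 0.73, Bola2, a factor of iron and sulfur cluster assembly, 3.31 ± 0.77 and Fastk, a kinase family member at mitochondria, 3.26 ± 0.20. At the other end, PRDM2 IP over input lay below the median probe at the odorant receptor gene Olfr441 (-1.17 ± 0.14), the globin gene Hbq1 (-1.08 ± 0.32), the myeloid surface antigen gene Ly6c (-1.06 ± 0.10), the mitochondrial import gene Timm8b (-1.05 ± 0.09) and the retinol dehydrogenase gene Rdh9 (-1.02 ± 0.35). The rule chose these 15 among promoters with a limma adjusted p under 0.05 and the same sign on both arrays.

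Of the 16164 promoters, limma called 7639 enriched and 184 depleted at an adjusted p under 0.05, beside 8570 and 323 at an unadjusted p under 0.05. Per probe, 11780 were called enriched and 9 depleted, beside 49240 and 15995 at an unadjusted p under 0.05. With loess the probe calls were 12658 and 5254. They fell to 0 each way with normexp, bright input, the value table, the GC trend removed or a variance trend. The split into higher and lower promoters followed the point taken as 0. With each array centred on its median probe, the median promoter lay at 0.57 and 0.43 on the PRDM2 arrays and at -0.24 on the H3K9me2 array; with the median promoter as 0, limma called 2769 promoters enriched and 2095 depleted. After the trend on probe GC content was removed, 2618 were enriched and 228 depleted, of which 2290 and 69 had the same call before. With normexp background correction limma called 0 promoters either way, beside 1512 higher and 450 lower at an unadjusted p under 0.05. Across the 16164 promoters the PRDM2 arrays correlated at Pearson r = 0.728 and Spearman rho = 0.715, and at r = 0.522 once the GC trend was removed; promoters of 1 array are not independent replicates.

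Among the gene groups fixed in advance, regulators of development and of chromatin carried more PRDM2 signal than other promoters by camera with its preset correlation, but not with an estimated correlation. In all, 17 of 31 lists passed by camera with the preset correlation. No list passed with an estimated correlation. That form of the test rests on the residual degrees of freedom of 2 arrays, so that hardly any list could pass and it cannot decide. For canonical histones the camera p went from 2.32e-08 to 0.0999, although their estimated correlation, -0.025, lay under the preset 0.01. Among the 17, the result was adjusted p = 0.612 with an estimated correlation for 13 lists, adjusted p = 0.671 with an estimated correlation for the methylation enzymes, and adjusted p = 0.708 with an estimated correlation for the neuronal, cytokine and keratin lists. Counts of enriched members are to be read beside 7639 of 16164 among all promoters. Of 85 promoters of developmental transcription factors, 71 were enriched (74 adjusted over the list alone), and their median lay 0.59 above that of all promoters (camera, adjusted p = 6.53e-08). Zic2, a factor of neural patterning, stood at 2.97 ± 0.39 and Foxc2, a factor of mesoderm and vessels, at 2.43 ± 0.40. Among 26 Polycomb genes 22 were enriched (23 adjusted over the list alone), with a shift of 0.49 (adjusted p = 0.000903 by camera); besides Pcgf2, Bmi1, another subunit of Polycomb repressive complex 1, reached 2.01 ± 0.11. The 26 histone lysine methylation enzymes shifted by 0.46 (camera, adjusted p = 0.00337), with 19 enriched (20 adjusted over the list alone); Prdm16, a PRDM family member of brown fat, had 2.37 ± 0.20 and Ehmt1, an H3K9 methyltransferase, 2.01 ± 0.32. Signalling genes moved the same way. The FGF pathway shifted by 0.43 (21 of 29 enriched, 24, and 1 depleted, adjusted over the list alone; camera adjusted p = 0.0135) with the ligands Fgf16 at 2.16 ± 0.06 and Fgf3 at 1.81 ± 0.18. The Wnt pathway shifted by 0.35 (37 of 50 enriched, 37 adjusted over the list alone; camera adjusted p = 0.00337) with the ligand Wnt4 at 2.32 ± 0.16 and the co-receptor Lrp5 at 1.74 ± 0.47. In the TGF-beta and BMP pathway 35 of 47 were enriched (35, and 1 depleted, adjusted over the list alone), with a shift of 0.30 (camera adjusted p = 0.00501); the inhibitors Smad7 and Nog stood at 2.48 ± 0.09 and 2.19 ± 0.105.

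By camera with its preset correlation, genes of cell cycle exit, neuronal, immediate early and Hox genes were higher too. CDK inhibitors and p53 targets shifted by 0.32 (17 of 25 enriched, 19 adjusted over the list alone, camera adjusted p = 0.0481), and after Cdkn2a the highest value was 1.52 ± 0.17 at Btg1, an antiproliferative gene. The list and its enriched members include Cdkn2a, whose ratio over low input does not show PRDM2 enrichment, and the test was not repeated without it. Neuronal genes shifted by 0.27 (21 of 30, 22 adjusted over the list alone; camera adjusted p = 0.0366), with the potassium channel gene Kcnc1 at 1.76 ± 0.62 and the stathmin gene Stmn3 at 1.53 ± 0.11. Immediate early genes shifted by 0.27 (18 of 28, 20 adjusted over the list alone; camera adjusted p = 0.0163), with the transcription factor genes Egr3 at 2.44 ± 0.30 and Klf2 at 1.60 ± 0.09. Hox genes shifted by 0.22 (20 of 32, 24 adjusted over the list alone; camera adjusted p = 0.0481), with Hoxd11 at 2.30 ± 0.58 and Hoxb5 at 1.34 ± 0.35. None of these 10 upward calls held with the GC trend removed, where the lowest camera adjusted p among them was 0.0694, for the developmental factors. The shifts then were 0.15 for developmental factors, 0.14 for FGF, 0.10 for neuronal, 0.08 for Hox, 0.07 for methylation, 0.05 for Wnt, 0.04 for Polycomb, -0.02 for TGF-beta and BMP, -0.04 for CDK inhibitor and -0.16 for immediate early genes. Median and test differed in sign there for the TGF-beta and BMP genes (mean 0.04, test upward), and median and mean for the CDK inhibitors (mean 0.02, test downward). Under normexp and loess the immediate early shift turned to -0.02 and -0.05, and the others shrank without turning, except that the Hox shift went from 0.22 to 0.12 and 0.24: CDK inhibitors to 0.03 and 0.01, neuronal genes to 0.04 and 0.11, Wnt to 0.10 and 0.10, TGF-beta and BMP to 0.12 and 0.28, FGF to 0.19 and 0.24, Polycomb to 0.20 and 0.15, methylation to 0.24 and 0.20 and developmental factors to 0.24 and 0.44. With the median over probes the calls of the CDK inhibitors and Hox genes ended (camera, adjusted p = 0.313 and 0.0916). Against random lists matched on GC content and probe number, the median of the developmental factors lay above all 10000 lists and that of the immediate early genes at percentile 1.23. The other 8 lay inside the middle 95%, at percentile 97.2 for methylation, 94.75 for FGF, 83.3 for Polycomb, 82.9 for neuronal, 81.8 for CDK inhibitor, 81.6 for Hox, 55.8 for TGF-beta and BMP and 39.8 for Wnt genes.

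Canonical histone, chemosensory receptor, liver, cytokine, keratin and mitosis genes carried less PRDM2 signal than other promoters by camera with its preset correlation, but not with an estimated correlation, and the receptor shifts turned upward with normexp, loess and the GC trend removed, as did the liver shift in the last and the histone shift with loess. Canonical histone genes, the replication-dependent clusters, shifted by -0.59 (camera, adjusted p = 1.8e-07). Of 29 promoters 2 were enriched, Hist1h4a at 1.395 ± 0.96 and Hist1h2ac at 0.95 ± 1.08, and 1 was depleted, Hist1h3f at -0.92 ± 0.43 (1 and 1 adjusted over the list alone). Hist1h4d at -0.48 ± 0.01 missed the limma threshold (adjusted p = 0.0629). Vomeronasal and olfactory receptors, the chemosensory receptors of the nose, shifted by -0.44 and -0.32 (camera, adjusted p = 5.96e-08 and 1.7e-09). Of 98 vomeronasal promoters 13 were enriched and 1 depleted (5 enriched adjusted over the list alone). Of 793 olfactory promoters 128 were enriched and 12 depleted (66 and 2 adjusted over the list alone). V1rc24 and V1rd7 stood at 1.74 ± 0.68 and 1.502 ± 1.102, and Olfr1129 and Olfr815 at 2.12 ± 0.52 and 1.97 ± 0.87, the last pair with input well above background at only 1 of 3 and 1 of 4 probes on PRDM2 array 1. Liver genes shifted by -0.42 (5 of 20 enriched, 4 adjusted over the list alone; camera adjusted p = 0.00874), with the apolipoprotein gene Apoa1 at 0.93 ± 0.62 and haptoglobin, Hp, at 0.82 ± 0.68. Cytokines and chemokines shifted by -0.39 (12 of 53, 11 adjusted over the list alone; camera adjusted p = 0.00337), with Il17b at 1.31 ± 0.04 and Cxcl14 at 1.23 ± 0.36. Keratins and skin genes shifted by -0.33 (5 of 27, 2 adjusted over the list alone; camera adjusted p = 0.00876), with Krt71 at 0.87 ± 0.48 and Krt8 at 0.81 ± 0.26. Krt71 and Krt8 turned negative with normexp and with loess, where Krt8 passed the limma threshold the other way (-0.47, adjusted p = 0.0199). Mitosis genes shifted by -0.28 (7 of 30 enriched and 2 depleted, 7 and 2 adjusted over the list alone; camera adjusted p = 0.00811), with the spindle checkpoint kinase gene Ttk at 1.20 ± 0.42 and the midbody motor gene Kif23 at 1.18 ± 0.21. With the GC trend removed the downward calls ended, although the mitosis shift stayed at -0.25 (camera, adjusted p = 0.0802), at percentile 0.11 of random lists of like probe number and 0.26 of lists matched on GC content too. The shift became -0.13 for canonical histones, -0.02 for cytokines, -0.02 for keratins, 0.07 for liver genes, 0.0045 for vomeronasal and 0.13 for olfactory receptors. The olfactory shift then passed upward with the preset correlation (camera, adjusted p = 0.0115) but not with the estimated one (adjusted p = 0.995 with an estimated correlation). The mitosis and liver calls also ended with the median over probes (camera, adjusted p = 0.076 and 0.11), and those of cytokines, liver and keratins with the highest 3 neighbouring probes (camera, adjusted p = 0.0655, 0.0655 and 0.448). The receptor shifts also turned upward under normexp (0.17 olfactory, 0.17 vomeronasal) and loess (0.12 and 0.10), and that of the histone genes ended at 0.0025 under loess. Among random lists matched on GC content too, the median of the olfactory receptors fell at percentile 99.8, and those of the canonical histones, cytokines and keratins at 1.03, 0.02 and 1.35. Those of the mitosis, liver and vomeronasal lists, at 13.34, 5.40 and 4.04, lay inside the middle 95%.

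On promoter means the muscle genes gave no call as groups by camera. With the highest 3 neighbouring probes the myogenic and satellite cell lists passed upward at the preset correlation (shifts 0.66 and 1.09; camera adjusted p = 0.0105 and 0.0166) but not with an estimated one (adjusted p = 0.425 and 0.646 with an estimated correlation). Among random lists of like probe number the medians of the myogenic, satellite cell and muscle structure lists fell at percentiles 97.8, 98.8 and 1.53. Matched on GC content too, they fell at 98.60, 94.02 and 1.56. On PRDM2 array 1 alone the myogenic and satellite cell lists were at 73.97 and 80.93. After removal of the GC trend the 3 lists were at 93.98, 30.24 and 94.79, with shifts of 0.13, -0.02 and 0.10, so that all 3 lay inside the middle 95% and those of the satellite cell and muscle structure lists had turned. Myogenic regulators shifted by 0.32 (18 of 30 enriched, 18 adjusted over the list alone; camera adjusted p = 0.0649), with the limb muscle factor Lbx1 at 1.91 ± 0.02 and the satellite cell factor Pax7 at 1.75 ± 0.60. The named muscle regulators were enriched by limma, Myog, which drives differentiation, at 1.06 ± 0.52 (adjusted p = 0.00239) and Myod1, which sets myoblast identity, at 0.90 ± 0.15 (adjusted p = 0.0032). Id3, an inhibitor of such factors, stood at 0.81 ± 0.00 (limma, adjusted p = 0.0054). None of these 3 passed with the median promoter as 0, and Id3 stood at -0.09 under loess. Ccna2, the cyclin of S phase and mitosis, had 0.44 ± 0.36 and did not pass (limma, adjusted p = 0.105). Prdm2 has no probes under that name and was not analysed here. Quiescent satellite cell genes shifted by 0.33 (16 of 29, 16 adjusted over the list alone; camera adjusted p = 0.328), with the Notch target Hey1 at 1.55 ± 0.05 after Bmi1. Genes of muscle structure and contraction shifted by -0.18 (19 of 53, 18 adjusted over the list alone; camera adjusted p = 0.312), with the calcium pump gene Atp2a2 at 1.81 ± 0.05 and M-cadherin, Cdh15, at 1.32 ± 0.26.

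The lists of proliferation genes other than mitosis gave no call by camera. The mitosis call itself ended with the median over probes (camera, adjusted p = 0.076). It also did not pass with an estimated correlation (adjusted p = 0.612 with an estimated correlation), a test that hardly any list could pass on 2 arrays. E2F and RB family genes shifted by 0.14 (12 of 18 enriched and 1 depleted, 12 and 1 adjusted over the list alone; camera adjusted p = 0.311), with E2f4 at 1.92 ± 1.03 and E2f6 at 1.88 ± 0.63. Cyclins and CDKs had a median of -0.06 and a mean of 0.07 relative to all promoters, with an upward test (10 of 23, 10 adjusted over the list alone; camera adjusted p = 0.968). Cdk6 stood at 1.78 ± 1.08 and Pkmyt1 at 1.77 ± 0.22. With loess Cdk6 passed the limma threshold the other way (-0.47, adjusted p = 0.0313). DNA replication genes shifted by -0.17 (15 of 38, 12 adjusted over the list alone; camera adjusted p = 0.412), with the clamp loader gene Rfc5 at 1.47 ± 0.98 and the single-strand binding gene Rpa1 at 1.39 ± 0.94.

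Of the remaining lists none passed on promoter means, and with the highest 3 neighbouring probes oxidative phosphorylation passed downward at the preset correlation (shift -0.44; camera adjusted p = 0.0367) but not with an estimated one (adjusted p = 0.425 with an estimated correlation). Imprinted genes shifted by 0.19 (21 of 31 enriched, 21 adjusted over the list alone; camera adjusted p = 0.256), with the growth factor gene Igf2 at 2.06 ± 0.27. Housekeeping genes shifted by 0.20 (16 of 27, 16 adjusted over the list alone; camera adjusted p = 0.266), with the elongation factor gene Eef2 at 1.78 ± 0.19. Oxidative phosphorylation genes shifted by -0.11 (24 of 64 enriched and 2 depleted, 21 and 1 adjusted over the list alone; camera adjusted p = 0.311), with the complex III gene Uqcrq at 1.57 ± 0.11, a value that became -0.69 without the GC trend. Immune cell genes shifted by -0.10 (10 of 33, 9 adjusted over the list alone; camera adjusted p = 0.328), with the T cell receptor chain gene Cd3g at 1.35 ± 0.05. As for the cyclins, the median, the mean and the camera test differed in sign in 4 more lists. Ribosomal proteins had a median of 0.10, a mean of -0.01 and an upward test (39 of 68 enriched and 1 depleted, 39 and 1 adjusted over the list alone; camera adjusted p = 0.995). Germline genes had 0.09, -0.01 and a downward test (17 of 34 enriched, 18, and 1 depleted, adjusted over the list alone; camera adjusted p = 0.968). Extracellular matrix genes had -0.01, -0.04 and an upward test (20 of 43 enriched, 19 adjusted over the list alone; camera adjusted p = 0.968). Zinc finger proteins had 0.02, 0.01 and a downward test (106 of 227 enriched and 3 depleted, 106 and 3 adjusted over the list alone; camera adjusted p = 0.985). Their first members by size were the ribosomal gene Rpl17 at 1.98 ± 0.97, the germ cell helicase gene Ddx4 at 1.44 ± 0.24, the protease inhibitor gene Timp2 at 1.62 ± 0.25 and Zfp341 at 2.70 ± 0.72. The microRNA list was not tested, since its only name on the array, Mir16, is an older symbol of the protein-coding gene Gde1.

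**Figure D1:**
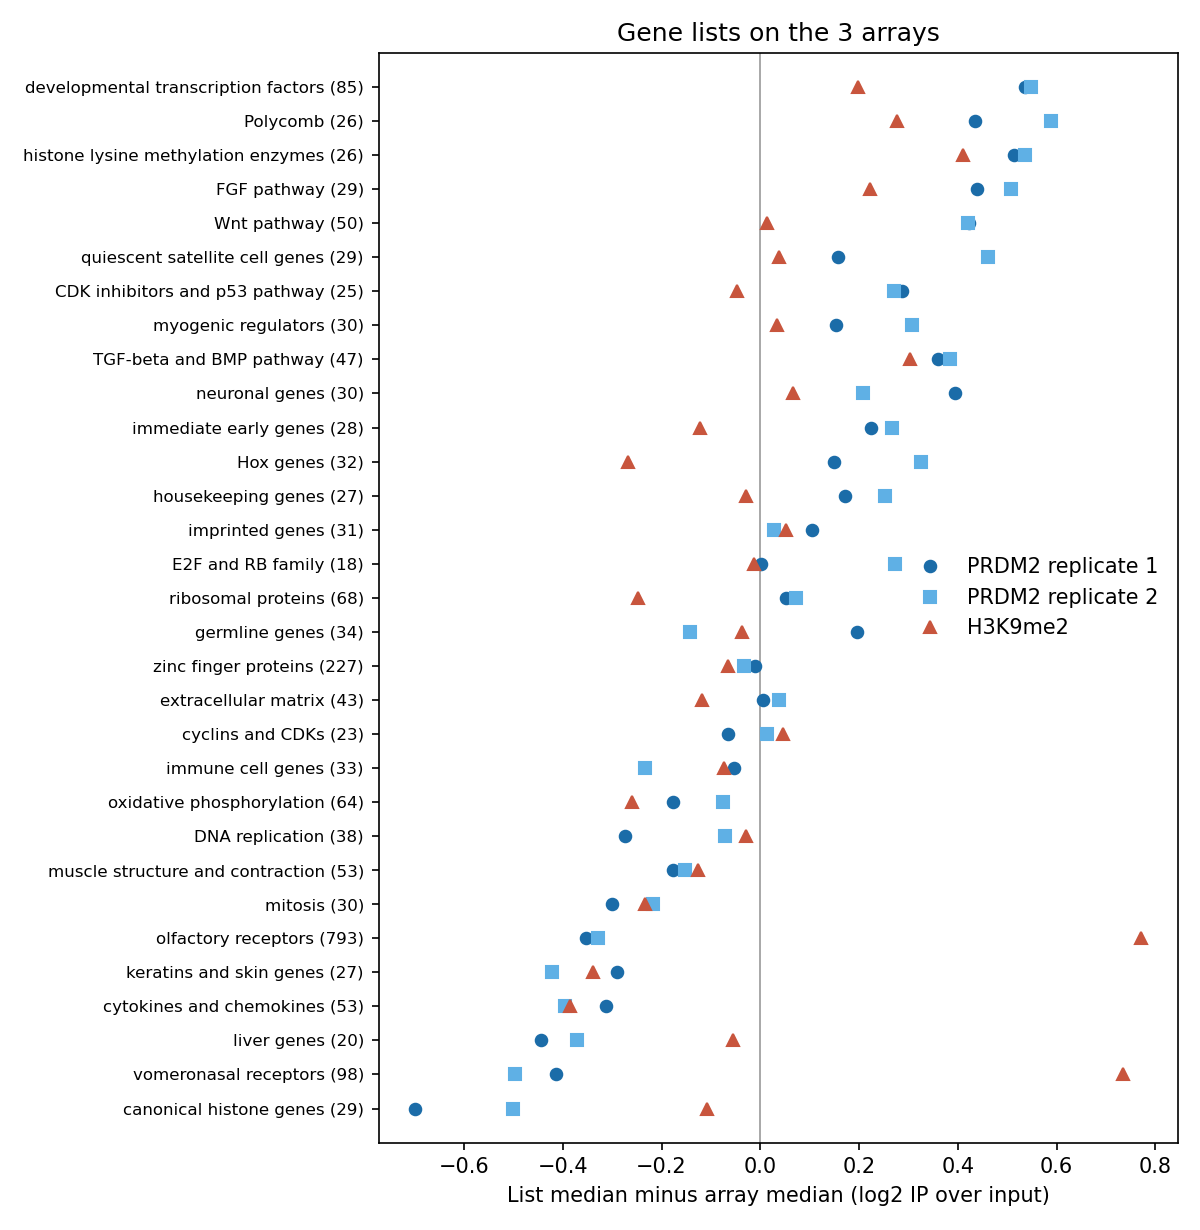
Median promoter of each gene list minus the median promoter of the same array, in log2 IP over input, for the 2 PRDM2 arrays (circles and squares) and the H3K9me2 array (triangles), with the number of promoters in parentheses. Developmental factors lay 0.59 above other promoters for PRDM2, a shift that became 0.15 with the GC trend removed and also shrank with normexp and loess. Olfactory receptors lay at -0.32 for PRDM2 and 0.77 for H3K9me2. These became 0.17 and -0.57 with normexp background correction, 0.12 and 1.33 with loess and 0.13 and 1.14 with the GC trend removed.

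Above 35% GC, IP over input rose with the GC content of the probe on every array. From probes of 35 to 40% GC to probes of 70% and over, the mean log2 ratio went from -0.02 to 4.14 on PRDM2 array 1, from -0.20 to 4.15 on PRDM2 array 2 and from -0.78 to 1.67 on the H3K9me2 array. Below 35% it went the other way, with means of 0.41, 0.47 and -0.20 under 30% GC and of 0.06, -0.06 and -0.43 from 30 to 35%, in 4222 and 17593 probes. Across promoters, the PRDM2 mean correlated with GC content at r = 0.645 and H3K9me2 at r = 0.0717. The developmental factor, Polycomb and Wnt promoters averaged 47.5%, 47.3% and 47.2% GC, beside 38.8%, 36.0% and 35.01% for the canonical histone, olfactory and vomeronasal promoters.

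**Figure D2:**
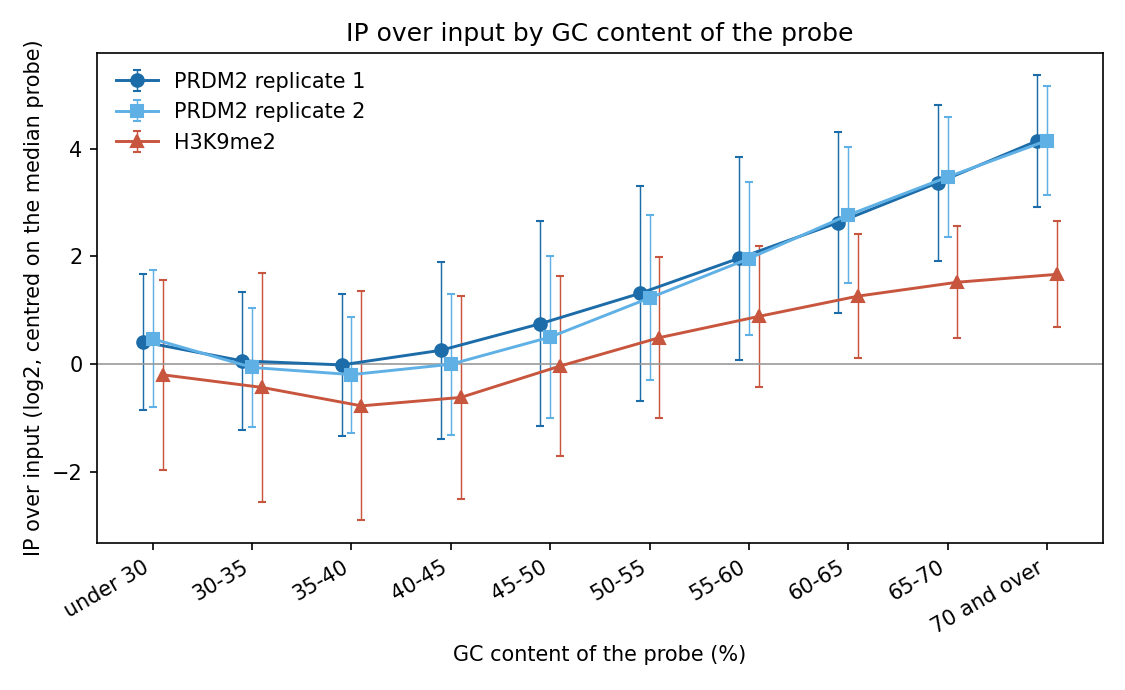
Mean log2 IP over input of the probes in classes of GC content on the 3 arrays, each centred on its median probe, with bars of 1 SD over probes. From 35% GC up the mean climbed to 4.14, 4.15 and 1.67 in probes of 70% GC and over on PRDM2 arrays 1 and 2 and the H3K9me2 array.

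The H3K9me2 array addressed where the mark lies that the PRDM2 domain is known to write. Among its highest promoters were those of 5 odorant receptors, 2 histocompatibility genes and 1 gene of the Y chromosome. Ddx3y, an RNA helicase gene on the Y chromosome, had a log2 IP over input of 2.92, followed by the histocompatibility gene H2-M1 at 2.87 and the odorant receptor gene Olfr707 at 2.73. Olfr380, Olfr293, Olfr955 and Olfr782 stood at 2.56, 2.53, 2.52 and 2.40, the class I gene H2-K1 at 2.45 and Bola2 at 2.44. Input on this array was well above background at 2 of 5 probes of Olfr707, 2 of 3 of Olfr380, 1 of 3 of Olfr293, 2 of 4 of Olfr955, 1 of 3 of Olfr782 and 8 of 11 of Ddx3y. These ratios rest in part on input near background, can be high at low IP signal and do not by themselves show H3K9me2. The input of chromosome Y was 0.106 of that of the autosomes. As a group the 793 olfactory receptor promoters lay 0.77 above the median promoter and the 98 vomeronasal promoters 0.73 above it, in both cases above all 10000 random lists of like probe number. Histone lysine methylation enzymes lay 0.41, TGF-beta and BMP genes 0.30 and developmental factors 0.20 above it, while cytokines (-0.38), keratins (-0.34), Hox genes (-0.27), oxidative phosphorylation genes (-0.26) and ribosomal protein genes (-0.25) lay in the lowest 2.5% of random lists. Matched on GC content too, the oxidative phosphorylation, ribosomal, keratin, TGF-beta, developmental and vomeronasal lists fell inside the middle 95%, at percentiles 9.63, 5.72, 5.78, 96.28, 84.63 and 72.39, although lists matched to vomeronasal promoters held many receptor promoters. The olfactory, methylation, cytokine and Hox lists stayed outside it, at 100, 98.43, 0.43 and 1.62. Among these lists only the receptors and cytokines, with the GC trend removed, lay outside the middle 95% of lists of like probe number. With 1 array none of this was tested. Under normexp the olfactory and vomeronasal shifts became -0.57 and -0.60 and the ribosomal shift 0.09. With the GC trend removed the receptor shifts were 1.14 and 1.05, while the developmental and TGF-beta shifts became -0.02 and -0.03. The Hox shift became 0.23 with the highest 3 neighbouring probes.

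Runs of neighbouring probes located the signal within promoters. For PRDM2, 45 runs of at least 3 probes lay above the 95th percentile of both arrays, with a median length of 383 bp and a median GC content of 71.9%. The highest 5 are given in the coordinates of the files, whose genome build is not given in the sources used here. They were at Tmem56 (chromosome 3, 121254552 to 121254888, log2 5.93 ± 0.07) and Hnrpab, an RNA-binding protein gene (chromosome 11, 51449777 to 51450140, 5.85 ± 0.36). The next were at Wnt4 (chromosome 4, 136549404 to 136549838, 5.59 ± 0.17), Pctk1, a cyclin-dependent kinase gene (chromosome X, 19845457 to 19845844, 5.59 ± 1.48), and Ube2o, a ubiquitin-conjugating enzyme gene (chromosome 11, 116397252 to 116397707, 5.57 ± 1.05). Shuffling the probes of each array independently gave 0 such runs, whereas shuffling both arrays together within classes of like GC content gave 22.3 on average, with a range from 14 to 38 in 100 shuffles. Once the GC trend was removed, 1 run was left, beside 0.54 on average and at most 3 after shuffling within GC classes. It lay at Slc13a2, a citrate transporter gene, which was named after its value was seen. The Slc13a2 promoter as a whole stood at 1.09 ± 0.38. For H3K9me2, 111 runs were found, beside 29.5 on average and at most 45 after shuffling within classes of like GC content, and 27 of them lay at olfactory receptor promoters. The shuffle did not match on input, whose median on this array was 106 at receptor probes beside 337 at other probes of like GC content. With normexp, only probes of bright input and loess, 80, 70 and 390 runs were found. The median GC content of the 111 runs was 36.7%.

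Promoters with PRDM2 and those with H3K9me2 overlapped in part. Of 43 promoters with a PRDM2 run, 5 also held an H3K9me2 run, beside 102 of all 16164 promoters and an overlap of 0.271 for independent sets. In 1000 shuffles matched on probe number and GC content the overlap averaged 0.416, with a highest of 3. The match was on the mean GC content of the whole promoter, 49.2 to 53.7% at these 5, beside 62.2 to 74.8% in their PRDM2 runs. It therefore does not account for GC content within the promoter. The 5 were a predicted gene, Hnrpab, Syncrip, an RNA-binding protein gene, Ppm1a, a phosphatase gene, and Hrk, an apoptosis activator gene, named after their values were seen because the count is small. Their PRDM2 means were 2.03 ± 0.38 at Hnrpab, 1.92 ± 0.31 at Syncrip, 1.45 ± 0.15 at Ppm1a and 1.28 ± 0.11 at Hrk, with H3K9me2 at 1.06, 0.35, 0.57 and -0.0023. With the GC trend removed the overlap was 0, but 1 PRDM2 run was left, so that this setting could not show an excess. With loess the overlap was 3 of 120 and 359 promoters, 1.13 times that of independent sets, so that the excess ended. In the main setting the overlap was 18.4 times that of independent sets, a ratio not matched on GC content. It was 29.99 times with normexp, 34.7 with bright input, 15.4 with the value table and 6.67 at the 90th percentile. Runs of at least 2 probes gave 3.37 times, and a log2 ratio of at least 1 gave 2.16. Runs of at least 4 probes and the 99th percentile left 5 and 0 promoters with a PRDM2 run, and 0 with both. Promoters high on all 3 arrays by the rule were, in alphabetical order, Arcn1, Bola2, Ddx3y, H2-K1, H2-M1, Jarid1d, Pcgf2, Tmem63b, Ube1y1 and Zfy1. Of these Ddx3y, Zfy1, Jarid1d and Ube1y1 are genes of the Y chromosome, where input was well above background at 2, 4, 3 and 3 of 11, 10, 12 and 13 probes on PRDM2 array 1, as it was at 1 of 5 probes of H2-M1. The ratios of these 5 rest on input near background and are imprecise, so that no order is given. High ratios over so little input do not by themselves show PRDM2 or H3K9me2 at these genes. Across all promoters the PRDM2 mean correlated with H3K9me2 at r = 0.525 and rho = 0.516. PRDM2 array 2, scanned on the same day as the H3K9me2 array, gave r = 0.464 alone, and PRDM2 array 1, scanned on another day, gave 0.510. With normexp the pooled value fell to r = 0.251.

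**Figure D3:**
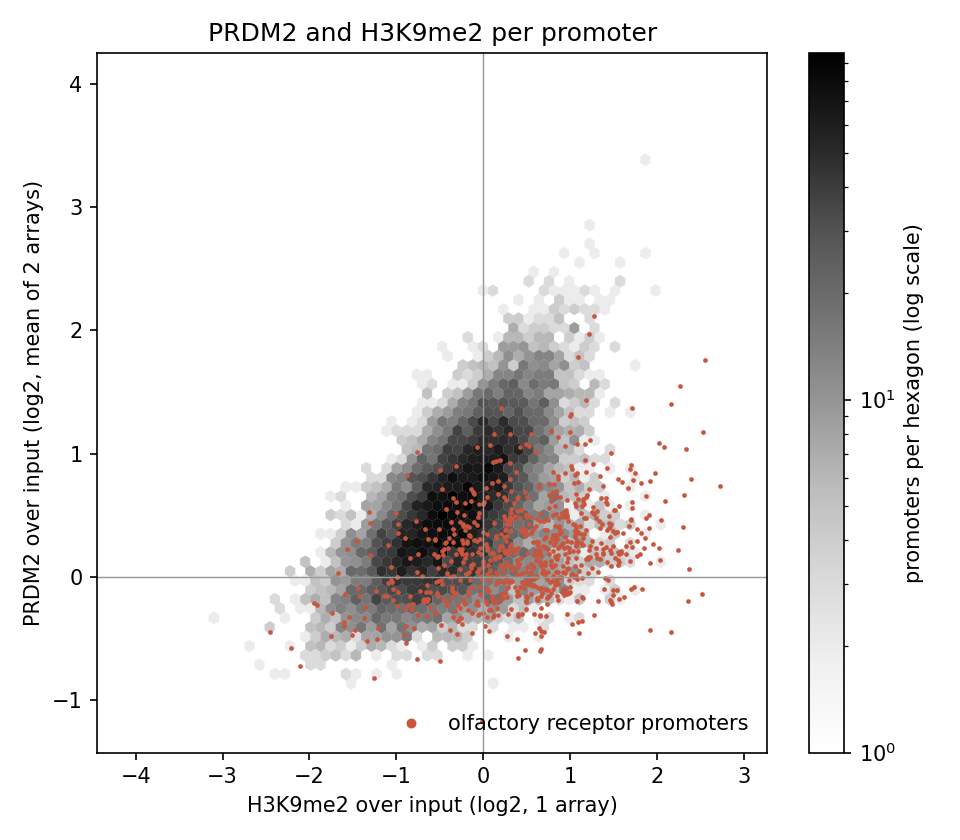
PRDM2 log2 IP over input (vertical, mean of 2 arrays) against H3K9me2 log2 IP over input (horizontal, 1 array) for 16164 promoters, as hexagons shaded by the number of promoters on a log scale, with olfactory receptor promoters as points. The correlation was r = 0.525 across promoters, and olfactory receptors lay to the right, 0.77 above the median promoter for H3K9me2, a shift that became -0.57 with normexp background correction.

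The difference of PRDM2 and H3K9me2 was greatest at genes of varied function with little H3K9me2 and at odorant receptors with much of it. At Nmnat1, which makes NAD in the nucleus, PRDM2 exceeded H3K9me2 by 3.39 ± 0.36 (limma SE), and at Plekha3, a Golgi adaptor, by 3.39 ± 0.37. It was lower at Nek8, a kinase of cilia (3.21 ± 0.59), Selenbp1, a selenium-binding protein (3.19 ± 0.35), and Ly6c (2.97 ± 0.35). Their H3K9me2 values were -4.09, -1.89, -3.02, -3.68 and -4.04, and among these 5 PRDM2 itself was called enriched only at Plekha3 (1.49 ± 0.40). In the other direction the difference was -2.66 at Olfr955, -2.62 at Olfr117, -2.55 at Olfr201 and -2.36 at Olfr386. Input of these on the H3K9me2 array was well above background at only 2 of 4, 1 of 4, 1 of 3 and 2 of 6 probes, so that these 4 differences are imprecise. The limma adjusted p of the 9 ran from 0.00446 to 0.00876 on the assumption that the lone H3K9me2 array varies as the PRDM2 pair does. That was not checked, and signal over background differed between the antibodies, so that these p-values do not include the spread of H3K9me2 itself. All 9 missed the threshold with the median over probes, the highest 3 probes, normexp, and the GC trend removed with centring. Among all promoters limma called 6817 with PRDM2 over H3K9me2 and 258 the other way, beside 8809 and 375 at an unadjusted p under 0.05. With the median promoter of each array as 0, these became 113 and 484. With normexp limma called 0 either way, beside 325 and 1487 at an unadjusted p under 0.05, and the differences at Ly6c and at the 4 named promoters with more H3K9me2 changed sign.

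Input DNA itself differed between chromosomes. Among probes of 35 to 50% GC, the median input signal on chromosome X was 0.490, 0.508 and 0.447 of that of all autosomes on PRDM2 arrays 1 and 2 and the H3K9me2 array, and on chromosome Y 0.039, 0.042 and 0.106. On chromosome 15 it was 1.60, 1.55 and 1.68, while the 18 other autosomes ranged from 0.88 to 1.08, from 0.90 to 1.07 and from 0.76 to 1.17. The log2 ratios moved the opposite way: relative to autosomes they were 0.24, 0.29 and 0.84 on chromosome X, 2.44, 2.70 and 3.19 on chromosome Y, and -0.14, -0.15 and -0.61 on chromosome 15. The values on chromosome Y are imprecise, since input was well above background at only 30.5%, 44.1% and 57.6% of its 59 probes. Ratios over so little input do not by themselves show enrichment. All 8 promoters on chromosome Y and 330 of 541 on chromosome X were called PRDM2-enriched by limma, beside 7639 of all 16164.

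**Figure D4:**
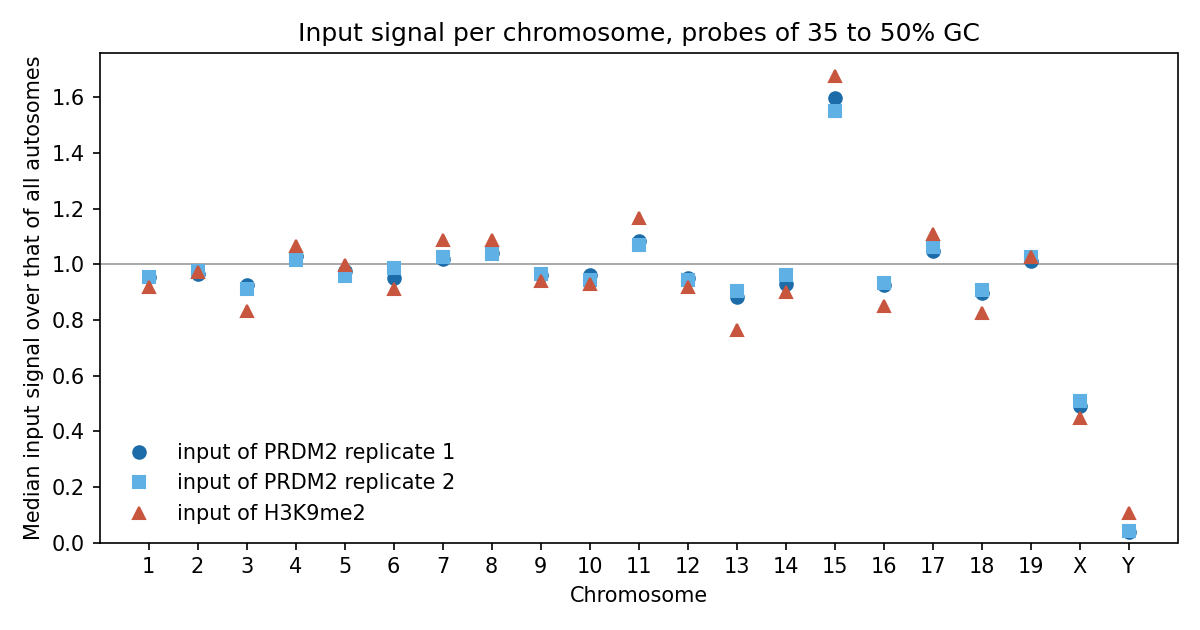
Median input signal of probes of 35 to 50% GC on each chromosome over that of all autosomes, for the inputs of the 3 arrays. Chromosome 15 stood at 1.60, 1.55 and 1.68, chromosome X at 0.490, 0.508 and 0.447 and chromosome Y at 0.039, 0.042 and 0.106.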

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

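The tests of low GC content and dim input for the olfactory receptors, and the separate reading of the PRDM2 and H3K9me2 arrays for IP signal near background, were chosen after the result was seen.

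PRDM2 and H3K9me2 differed in the limma test of the difference at 6817 promoters with more PRDM2 and at 258 with more H3K9me2, on the assumption, not checked, that the lone H3K9me2 array varies as the PRDM2 pair does. With the median promoter of each array as 0 these counts became 113 and 484, with loess 664 and 1489, and with normexp limma called 0 either way (325 and 1487 at an unadjusted p under 0.05). The promoters of the naming rule that met it were those of Nmnat1 (3.39), Plekha3 (3.39), Nek8 (3.21), Selenbp1 (3.19) and Ly6c (2.97), and in the other direction Olfr955 (-2.66), Olfr117 (-2.62), Olfr201 (-2.55) and Olfr386 (-2.36). The last 4 are imprecise, since input on the H3K9me2 array was well above background at 2 of 4, 1 of 4, 1 of 3 and 2 of 6 probes. The shifts of 2 receptor families pointed opposite ways on the arrays of both antibodies: olfactory receptors lay at -0.32 for PRDM2 and 0.77 for H3K9me2, and vomeronasal receptors at -0.44 and 0.73. These shifts were not tested against each other, and with normexp they became 0.17 and -0.57 for olfactory and 0.17 and -0.60 for vomeronasal receptors. The opposite signs ended with loess, at 0.12 and 1.33 for olfactory and 0.10 and 1.34 for vomeronasal receptors. They also ended with the GC trend removed, at 0.13 and 1.14 and at 0.0045 and 1.05. In both settings the H3K9me2 shift stayed the higher of each pair.

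Above 35% GC, IP over input rose with the GC content of the probe on all 3 arrays. CpG density was tested as a biological explanation by CpG pairs within the probe sequence only. Among probes of like GC content, those with the most differed from those with the fewest by -0.586 ± 0.011 on the H3K9me2 array. They were lower on the PRDM2 arrays too, which argues against CpG pairs of the probe itself. CpG density of the surrounding promoter was not measured and stays open. IP signal near background is argued against on the PRDM2 arrays, where probes with IP well above background kept 0.998 ± 0.007 of the slope. The slope under normexp, which treats background otherwise, was not measured. On the H3K9me2 array IP signal near background stays open, at 0.808 ± 0.016, within its spread of the bound of 0.8. The slope on the probe's own GC content, with the GC content of its neighbours in the same fit, was at least 0.0867 ± 0.0011 per percent on every array, which is consistent with an effect of the base composition of the probe itself. No other biological explanation was tested.

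After the GC trend was removed, the H3K9me2 array still correlated with the PRDM2 arrays probe by probe, at r = 0.513 and 0.421, beside 0.493 between the PRDM2 arrays. PRDM2 and H3K9me2 on the same chromatin fragments stay open. Neighbouring probes within 200 bp kept only 0.0877 ± 0.010 of the correlation across the antibodies, which had been set down as evidence against shared fragments. But the PRDM2 arrays kept only 0.062 between themselves, so that the test cannot tell shared fragments from separate ones. Effects of single probes shared by all arrays stay open: among probes of like GC content and input signal, 0.981 ± 0.003 of the correlation was kept, which had been set down as evidence against them. That bound was wrong, because a probe effect need not run through GC content or input signal, and the correlation was confined to single probes. This reading was decided after the values were seen.

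H3K9me2 was higher at olfactory receptor promoters than at other promoters except under normexp, where the shift was -0.57. As the whole cause, low GC content is argued against by a difference of 0.422 ± 0.079 from promoters of like GC content, and dim input by 0.564 ± 0.056 between probes of like GC content and input. Under normexp, receptor probes still lay 0.180 ± 0.016 above probes of like GC content and input, which had been set down as evidence against the subtraction of background. That prediction was written before this value but after the shift under normexp was seen. It bears only on the difference between matched probes, and the input matched on was itself background-subtracted. For the shift over all promoters, which turned to -0.57, the subtraction of background stays open. A domain of H3K9me2 that takes in other genes of the receptor clusters is argued against: promoters of other genes within 200 kb lay -0.0203 ± 0.060 from promoters of like GC content farther away, which is under the bound of 0.1, set beforehand, by more than the standard error, although by slightly less than the 2 standard errors that the script asks for. A mark confined to the receptor genes was not tested. The technical effects together stay open, and no replicate of this array was used here.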

How the results depend on the processing

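The tests with centring on the median promoter, with the GC trend removed from regions, with random lists matched on GC content and of list medians under normexp, loess, dim probes and the value table were chosen after the result was seen.

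With normexp limma called 0 promoters PRDM2-enriched and 0 depleted (1512 and 450 at an unadjusted p under 0.05), 0 and 0 in the difference (325 and 1487) and 0 and 0 probes (17181 and 23703); the correlation of the PRDM2 arrays was 0.437 and that of PRDM2 with H3K9me2 0.251, and 29 PRDM2 regions were found. With loess the counts were 3476 and 1235 promoters, 664 with more PRDM2 and 1489 with more H3K9me2, 5254 depleted probes, 127 PRDM2 and 390 H3K9me2 regions and 3 promoters with both, 1.13 times the overlap of independent sets, with correlations of 0.704 and 0.609. With only probes of bright input the correlations were 0.715 and 0.602, 169 promoters had more H3K9me2, 70 H3K9me2 regions were found, and limma called 0 probes either way (46622 and 15069 at an unadjusted p under 0.05). With the value table of the series, 277 promoters were depleted, 4431 had more PRDM2, the replicate correlation was 0.697 and limma called 0 probes either way (46057 and 11922). With the GC trend removed 2618 promoters were enriched and 822 had more PRDM2, the replicate correlation was 0.522, limma called 0 probes either way (27012 and 17042), and 1 PRDM2 region, 182 H3K9me2 regions and 0 promoters with both were found, the last without a test. The cause was not tested for any of these.

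With the median over probes 884 promoters were enriched and 13 depleted, the replicate correlation was 0.652 and limma called 0 differences either way (2751 and 990 at an unadjusted p under 0.05). With the highest 3 neighbouring probes 13339 were enriched and 6 depleted, since a maximum is taken, the correlations were 0.745 and 0.589 and limma called 0 differences either way (3656 and 246). With at least 5 probes the replicate correlation was 0.734. With the median promoter as 0 the counts were 2769 and 2095, and 113 and 484 in the difference, since the point of 0 moves. Removing the GC trend as well gave 50 and 18, and limma called 0 differences either way (966 and 1517). A variance trend gave 303 depleted promoters and 0 probes either way (45874 and 25469 at an unadjusted p under 0.05), and an adjusted p under 0.10 gave 352 depleted promoters, 397 with more H3K9me2, and 31496 enriched and 1659 depleted probes, since the threshold is wider. The cause was not tested where none is given.

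Regions followed the threshold by construction. The 99th percentile gave 0 PRDM2 regions, 1 H3K9me2 region and 0 promoters with both, a rule without a test; the 90th gave 394, 485 and 71; a log2 ratio of at least 1 gave 4283, 5429 and 2467; at least 2 probes gave 366, 953 and 64; and at least 4 probes gave 5, 12 and 0. Leaving out each PRDM2 array in turn gave 154 to 382 PRDM2 regions and 8 to 17 promoters with both, since 1 array then decides, and correlations with H3K9me2 of 0.464 to 0.510.

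With the GC trend removed camera found 1 list past the threshold, and with an estimated correlation 0 lists, where the lowest adjusted p was 0.612. With the median over probes camera kept 13 of the 17 calls, and those of CDK inhibitors, Hox, mitosis and liver genes ended (adjusted p = 0.313, 0.0916, 0.076 and 0.11 by camera). With the highest 3 neighbouring probes it kept 14, those of cytokines, liver and keratins ended (adjusted p = 0.0655, 0.0655 and 0.448 by camera), and the myogenic, satellite cell and oxidative phosphorylation lists were gained (adjusted p = 0.0105, 0.0166 and 0.0367 by camera). For PRDM2, 17 lists lay outside the middle 95% of random lists, 9 when matched on GC content too and 4 with the GC trend removed; for H3K9me2 there were 10, 5 and 5. Leaving out each PRDM2 array gave 15 to 16 for PRDM2. All 17 lists kept their direction without each PRDM2 array.

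The following values changed sign, and the cause was not tested. With the GC trend removed the PRDM2 shift was -0.039 for CDK inhibitors, 0.0712 for liver, -0.16 for immediate early, 0.13 for olfactory and 0.0045 for vomeronasal genes, the H3K9me2 shift was -0.015 for developmental factors and -0.032 for TGF-beta and BMP genes, and Uqcrq stood at -0.69. With centring as well the values were -0.22 at Foxc2, -0.14 at Stmn3, -0.0053 at Krt8, -0.92 at Uqcrq, -0.12 at Hrk and -0.0014 at Ppm1a. The H3K9me2 shift of Hox genes was 0.23 with the highest 3 neighbouring probes. With normexp the H3K9me2 shift was 0.088 for ribosomal, -0.57 for olfactory and -0.60 for vomeronasal genes, the PRDM2 shift was -0.016 for immediate early, 0.17 for olfactory and 0.17 for vomeronasal genes, and PRDM2 was 0.059 at Olfr441, -0.19 at Krt71 and -0.085 at Krt8. The differences under normexp were -0.28 at Ly6c, 0.40 at Olfr955, 0.50 at Olfr117, 0.053 at Olfr201 and 0.79 at Olfr386. With loess the PRDM2 shift was 0.0025 for canonical histones, -0.048 for immediate early, 0.12 for olfactory and 0.10 for vomeronasal genes, and PRDM2 was -0.086 at Id3, -0.080 at Hp, -0.39 at Krt71, -0.47 at Krt8, -0.47 at Cdk6, -0.14 at Cdh15 and -0.35 at Slc13a2.

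Of 90 named promoters past the limma threshold, 90 stayed past it with outlier spots kept and with a variance trend, 84 with the highest 3 probes, 79 with centring, 74 with loess, 67 with the GC trend removed, 42 with the median over probes, 16 with the GC trend removed and centring and 0 with normexp (limma; none was tested without a PRDM2 array, where all 90 kept their sign). All 79 that had enough probes of bright input and all 83 in the value table stayed past it. The 9 named differences stayed past it with the GC trend removed, centring, loess, outlier spots kept, the value table and a variance trend, and 5 of 5 with bright input. All 9 missed it with the median over probes, with the highest 3 probes, with the GC trend removed and centring, and with normexp, where 5 changed sign.

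Signal over background was lower on the PRDM2 arrays, where the median IP was 1.47 and 1.39 times that of the negative controls, than on the H3K9me2 array, at 6.44 times. No paired analysis was possible because each IP shares its array only with its own input and no number in the labels pairs the arrays. The slide as a block was not run, since each slide holds 1 array, and the scan day as a block leaves no residual degrees of freedom. The profile over distance to the transcription start, also in narrower bins, was not run, since the build of the coordinates is not given in the sources used here.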

Other observations

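The tests of input levels were chosen after the result was seen, and the promoters in them were named after their values were seen.

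Input DNA was low at a few promoters on every array. Among 15673 promoters with at least 5 probes, 13 had an input signal over 2 log2 units below that of probes of like GC content on all 3 arrays, and limma called all 13 PRDM2-enriched. They included the taste receptor gene Tas2r120 at -4.61, -5.002 and -4.10, the cell cycle inhibitor gene Cdkn2a at -4.22, -3.99 and -3.52, the Y chromosome genes Uty, Zfy1, Sry and Ube1y1, the histocompatibility gene H2-M1, Pet2 on chromosome X and the receptor genes Olfr290, Olfr291 and V1rc20. With so little input the ratio at these promoters is imprecise, can be high at low IP signal and does not show PRDM2 enrichment. Input was over 2 log2 units higher on all arrays at Cd244, Trpm8 and Sfi1, the last at 3.33, 3.78 and 3.14. No explanation of these levels was tested.

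Neighbouring probes within 200 bp carried little common signal once the GC trend was removed. The correlation of a probe with its neighbour was 0.047 and 0.053 within PRDM2 arrays 1 and 2 and 0.120 within the H3K9me2 array, and 0.0307 between the PRDM2 arrays, beside 0.493 for the same probe.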
